A study of Mus musculus with 8 samples.

How the data were processed

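Liver RNA of 8-week-old ICR scid mice was compared on 8 two-colour Agilent 4x44k v1 mouse arrays. Each array held 2 pools of RNA, and each of the 4 comparisons had 2 arrays with separate pools of mice and with the dyes reversed. The comparisons were untreated males over untreated females, and Adeno-Cux2 over Adeno-CMV in males 5 days, females 5 days and males 3 days after treatment. Adeno-Cux2 is an adenovirus that carries Cux2, and Adeno-CMV is the control adenovirus. RNA was extracted with Trizol, amplified to aminoallyl RNA and coupled to green or red Alexa dyes, per the labels. The series text gives 11 untreated females and 3 experiments, while the sample labels used here give 10 and 4. The female arrays, female by title, source and sex label, carry a stated purpose that names males. Replicate 1 carried the numerator pool in red and replicate 2 in green.

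The scanner files were made with Agilent Feature Extraction, version 9.5.3.1 for the untreated and male day 5 arrays and version 10.7.1.1 for the female day 5 and male day 3 arrays, per the file headers. The deposited intensity values are the median pixel brightness of each spot and of its local background in each channel, with no normalization. The deposited LogRatio column is the log10 ratio of red to green after the software's background subtraction and dye normalization, per the file headers. The deposited series matrix holds log10 ratios, and each of its columns equals that LogRatio with the sign turned on replicate 2, to within 5e-06. The deposited spot flags are values of 0 or 1, per the file headers, for signals well above background, saturated spots and outlier spots. The annotation of the array is on mm8. The untreated and male day 5 arrays shared 1 slide, and the female day 5 and male day 3 arrays the other.

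All 8 arrays were processed again from the median signals, since mean signals were not in the files of every array. Local background was subtracted by normexp with an offset of 50, and log2 ratios were normalized within each array by loess in limma 3.58.1 with the package data.table at version 1.17.8 and R at 4.3.3. Control spots and outlier spots had a weight of 0 in the loess curve. Of 43379 gene spots and 1639 control spots, the gene spots gave 41174 probes. A probe was kept if it was well above background in at least 1 channel on both arrays of at least 1 comparison, which left 33330. Names came from the reference table of mouse genes on GRCm38, with 24375 probes matched by accession, 6301 by symbol and 2426 by synonym. The other 8072 kept the name in the files. The probe with the highest mean intensity stood for a gene, giving 22220 genes, of which 7548 (34.0%) had several probes. Among called genes with several probes, all probes had the same direction for 78.5% in the untreated comparison, 84.4% in male day 5, 84.8% in female day 5 and 80.5% in male day 3.

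Median signals per array were 343 to 442 in green and 430 to 512 in red, over local backgrounds of 289 to 315 and 327 to 342.5. Spots well above background made up 68.2% to 76.7% in green and 71.7% to 80.1% in red. Saturated spots numbered 0 to 16 per array and outlier spots 100 to 130. The median standard error of a log2 ratio was 0.0784 for a comparison and 0.111 for a difference between 2 comparisons.

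One limma model was fitted to all 8 arrays, with a coefficient for each comparison and a term for the dye, so that the comparisons shared 3 residual degrees of freedom and a prior of 3.63. Moderated tests were 2-sided and adjusted by Benjamini and Hochberg over all genes, and a gene was called at an adjusted p under 0.05. Errors after ± are standard errors of that model, and n is 2 arrays per comparison. The error covers the spread between pools, not that between mice. The female response at day 5 was tested against the male response at day 5, and the male response at day 5 against that at day 3, as contrasts in the same model. The arrays of each contrast lie on both slides, so the slide cannot be separated from these differences.

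A total of 26 gene lists, written from textbook knowledge and not chosen on these samples, were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Adjustment was over the 26 lists within a comparison, on the 22205 genes with a value on every array. Camera compares a list with all other genes, and fry tests whether its members move, on balance, one way. They covered sex-biased liver genes, growth hormone signalling, transcription factors, interferon, acute-phase and stress responses, the cell cycle, metabolism, secreted proteins, and markers of other cells and tissues. A list of 53 skeletal muscle markers was added after the values were seen. Genes called in the untreated comparison were also followed as 2 sets, and their 6 set tests were adjusted together.

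Named genes were taken by a fixed rule. It took, for each comparison, the 8 largest rises and the 8 largest falls among called genes that were bright and moved the same way on both arrays, up to 2 called members per direction of each list, Cux2, the sex chromosome genes, 4 sex-biased genes of each kind that responded, and 4 genes per direction of each difference. The rule took 367 pairs of a gene and a comparison, and 204 are given, chosen mainly as those whose call held with every array left out in turn. A few others that the rule took are not reported here. The lists apart from the muscle markers, the model, the threshold, the naming rule and the alternatives but 1 (fry without the dye term) were chosen before the data were examined.

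The steps were tested on simulated signals, with the spread and dye effect fitted to each gene. Of 67 genes changed 1.5-fold, 63 (94.0%) were recovered in untreated mice and 59 (88.1%) in male day 5. In female day 5 and male day 3 they were 58 (86.6%) and 53 (79.1%). Unchanged genes made up 8.02%, 6.37%, 5.47% and 5.10% of the calls in the same order. A changed list in male day 5 had a p of 3.93e-110 by preset camera, 0.000133 by estimated camera and 3.28e-07 by fry. By each, 0 of 50 unchanged lists had a p under 0.05. The fit was per gene and few genes changed, so correlation within lists and loess under broad change are not covered.

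Alternatives changed 1 choice at a time, except that the software's values change background and normalization together and 2 arrays alone have no dye term. They were no background subtraction, the software's LogRatio, the series matrix values, median centring in place of loess, no filter on dim probes, both channels above background on all 8 arrays, saturated spots set to missing, the mean of all kept probes of a gene, no dye term, a dye term per slide, the 4 arrays of a slide alone, the 2 arrays of a comparison alone, an intensity trend with a robust prior, an added 1.5-fold threshold, and leaving out each of the 8 arrays. Where an array was left out, the remaining one of its comparison was assumed to vary like the others. With 2 arrays per comparison, other splits of the samples and tests for an outlying array were not run.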

Results

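The data were 8 two-colour arrays of liver RNA, 2 for each of 4 comparisons. Untreated males were compared with females (10 mice each), and Adeno-Cux2 with Adeno-CMV. Treated mice were males at day 5 (12 and 13), males at day 3 (11 and 11) and females at day 5 (8 and 7). Each array carried a separate pair of pools of 3 to 7 mice, so n is 2 arrays throughout and values are log2 ratios ± standard error. Across genes, which are not independent replicates, the 2 arrays of a comparison correlated at a Pearson r of 0.612 in untreated mice, 0.873 in males at day 5, 0.678 in females at day 5 and 0.893 in males at day 3.

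Cux2, a homeobox transcription factor, passed the test in all 4 comparisons. It was lower in untreated males, at −1.88 ± 0.09 (3.67-fold lower, adjusted p = 0.000182). In males the pools labelled Adeno-Cux2 were higher, by 0.60 ± 0.09 at day 5 (1.52-fold, adjusted p = 0.0043) and 0.49 ± 0.09 at day 3 (1.40-fold, adjusted p = 0.00439). In females the pools labelled Adeno-Cux2 were lower, at −0.61 ± 0.09 (1.53-fold lower, adjusted p = 0.0045), on both arrays (−0.58 and −0.65). These values come from a probe at 122121055 to 122121114 of chromosome 5 on mm8, and a further probe at 122156086 to 122156145 gave −1.31, 0.31, −0.33 and 0.43 for the untreated, male day 5, female day 5 and male day 3 arrays. Whether either probe lies in the part of Cux2 carried by the virus is not stated, so they need not read the transgene. The calls in treated mice were lost without an own array (adjusted p = 0.0963 and 0.119 in males at day 5, 0.0650 and 0.0561 in females, and 0.102 in males at day 3 without replicate 2), without background subtraction (0.169, 0.0581 and 0.188 for male day 5, female day 5 and male day 3) and with median centring (0.0892, 0.0540 and 0.0718). The size of the Cux2 values depends on the background step: untreated, male day 5, female day 5 and male day 3 values were −0.98, 0.17, −0.28 and 0.13 without background subtraction, and −2.63, 1.77, −0.92 and 1.46 with the software's log ratios.

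**Figure D1:**
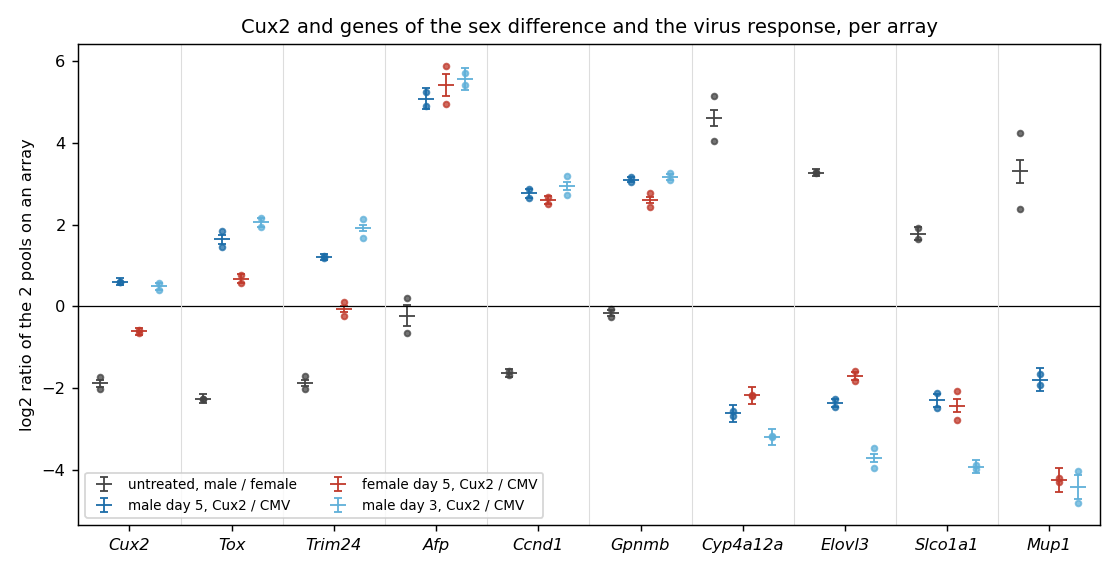
Log2 ratios of 10 genes in the 4 comparisons, as single arrays and mean ± standard error (n = 2 arrays). The error is that of the model of all 8 arrays, shared by the 4 comparisons. It can thus differ from the spread of the 2 arrays shown. Cux2 in females at day 5 lies below 0 on both arrays (−0.58 and −0.65), while Afp lies between 4.91 and 5.88 on all 6 arrays of treated mice.

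Single enzyme and transporter genes differed between the untreated sexes. Cyp4a12a, a fatty acid hydroxylase, was higher in males by 4.60 ± 0.20 (24.3-fold), Elovl3, an elongase, by 3.27 ± 0.09, Cyp7b1, an oxysterol hydroxylase, by 3.08 ± 0.10, and Nat8f5 by 4.22 ± 0.11. Sult3a1, a sulfotransferase, stood lower in males at −8.38 ± 1.27 and Hao2, a hydroxyacid oxidase, at −5.04 ± 0.39. The cytochromes Cyp2b9 and Cyp2b13 stood at −3.56 ± 0.21 and −3.07 ± 0.20. Other genes lower in males were Sult2a2 (−5.40 ± 0.96) and the transporters Slc22a26 and Slc22a29 (−5.25 ± 0.59 and −4.65 ± 0.22). The Y-linked Eif2s3y, Ddx3y, Kdm5d and Uty were higher in males by 6.02 ± 0.17, 5.83 ± 0.08, 3.63 ± 0.09 and 2.67 ± 0.18. Xist, of the inactive X chromosome, stood at −5.83 ± 0.57. Uty depends on the background offset, and the others vary over the alternatives (Kdm5d 2 to 5.53). In all, 1097 of 22220 genes were higher in males and 1366 lower (limma), 160 and 162 of them by at least 2-fold. Without replicate 1 the counts were 286 and 249, without replicate 2 they were 1562 and 2410, and without either male day 5 array 555 and 643. The calls of Sult3a1, Xist, Slc22a26 and Sult2a2 were lost without replicate 1 (adjusted p = 0.179, 0.0548, 0.0856 and 0.235) and with the software's log ratios (0.0788, 0.0758, 0.0562 and 0.0952). That of Sult2a2 was also lost without replicate 2 (0.0596) and without background subtraction (0.0520), and those of Sult3a1 and Sult2a2 with an intensity trend (0.0948 and 0.121).

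Known sex-biased genes differed between the untreated pools. After each list, "alone" stands for adjusted over the list alone. Of 47 known female-biased genes 38 were lower in males and 3 higher (5 higher and 39 lower alone, median −1.84, adjusted p = 4.67e-21). Female-biased genes had adjusted p = 0.179 with estimated correlation. They included Tox and Trim24, transcriptional regulators (−2.26 ± 0.11 and −1.87 ± 0.08), and Prlr, the prolactin receptor (−1.24 ± 0.11). Adh6-ps1 and Aqp4 of the same list were higher in males (2.42 ± 0.07 and 0.99 ± 0.06), at 1.22 to 3.61 and 0.44 to 1.44 over the alternatives. Of 50 known male-biased genes 37 were higher in males and 3 lower (40 and 3 alone, median 1.19, adjusted p = 7.18e-27). Slco1a1 stood at 1.77 ± 0.16 and Wfdc2, which went the other way, at −0.82 ± 0.07. Male-biased genes had adjusted p = 0.30 with estimated correlation. All 6 genes of the major urinary protein list, 5 Mup genes and Obp2a, were higher in males (6 adjusted over the list alone, median 2.33, adjusted p = 1.29e-07), Mup1 by 3.30 ± 0.29. Urinary protein genes had adjusted p = 0.469 with estimated correlation. Probes for Mup, Cyp2b, Sult2a, Sult3a, Cyp4a12 and Slc22a genes can also read close relatives. Of 34 complement and coagulation genes 7 were higher, including C6 and C9 of the terminal pathway (3.49 ± 0.15 and 1.84 ± 0.14), and 5 lower (9 and 7 adjusted over the list alone, median 0.03, −0.02 without background subtraction and just below 0 with median centring, adjusted p = 0.520).

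Cell cycle, inflammatory and immune cell lists lay lower in untreated males. Of 43 cell cycle genes 14 were lower and 1 higher (1 higher and 22 lower alone, median −0.26, adjusted p = 6.17e-08). Ccnd1, cyclin D1, stood at −1.64 ± 0.10. Cell cycle genes had adjusted p = 0.492 with estimated correlation. Of 28 acute-phase genes 9 were lower and 2 higher (4 higher and 11 lower alone, median −0.23, adjusted p = 0.000133). Orm3 stood at −2.16 ± 0.11 and Mt2 at −2.04 ± 0.22. Acute-phase genes had adjusted p = 0.492 with estimated correlation. Of 25 macrophage markers 9 were lower and 1 higher (2 higher and 17 lower adjusted over the list alone, median −0.36, adjusted p = 7.53e-06), among them Cd163 (−0.83 ± 0.08), whose call was lost with the software's log ratios (adjusted p = 0.0736) and with the 2 arrays alone (0.0901). Macrophage markers had adjusted p = 0.492 with estimated correlation. Of 43 interferon-stimulated genes 9 were lower (10 adjusted over the list alone, median −0.09, adjusted p = 0.0068), including Gbp2 and Gbp3 (−1.57 ± 0.09 and −1.60 ± 0.13). Interferon genes had adjusted p = 0.726 with estimated correlation. Of 39 PPAR-alpha and fatty acid oxidation genes 10 were lower and 2 higher (2 higher and 13 lower adjusted over the list alone, median −0.14, adjusted p = 0.015), Acot3 at −3.07 ± 0.16. PPAR-alpha genes had adjusted p = 0.492 with estimated correlation. Lists with fewer called members were p53 targets with 7 of 22 lower (1 higher and 8 lower adjusted over the list alone, median −0.15, adjusted p = 0.0016), neutrophil markers with 4 of 14 lower (5 alone, median −0.30, adjusted p = 0.00438), and hepatocyte identity genes with 5 of 30 lower (9 alone, median −0.23, adjusted p = 0.00172). The p53 targets and neutrophil markers had adjusted p = 0.492 with estimated correlation, and hepatocyte genes 0.619. T and natural killer markers had 5 of 26 lower and 1 higher (2 higher and 7 lower alone, median −0.12, adjusted p = 0.0219). Stellate cell markers had 4 of 22 lower (4 alone, median −0.12, adjusted p = 0.0219). Endothelial markers had 2 of 19 lower (2 alone, median −0.11, adjusted p = 0.0353). Cholesterol genes had 1 of 25 lower (1 alone, median −0.15, adjusted p = 0.0353, but 0.447 by fry), against 11.1% of all genes called. T cell markers, short for this T and natural killer list, had adjusted p = 0.663 with estimated correlation. Stellate markers and cholesterol genes had 0.726 and endothelial markers 0.509.

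In the lists that missed the set test in untreated mice (adjusted p = 0.0655 to 0.666), the members higher and lower in males were 5 and 15 of 36 xenobiotic genes (9 and 16 adjusted over the list alone), 2 and 7 of 33 transcription factors (2 and 7), 5 and 6 of 29 bile acid genes (7 and 8), 2 and 5 of 27 fatty acid genes (2 and 6), 1 and 3 of 17 growth hormone genes (2 and 3), 2 and 1 of 26 unfolded protein genes (2 and 1), 0 and 2 of 17 cholangiocyte markers (0 and 2), 2 and 0 of 15 red blood cell genes (2 and 0) and 1 and 1 of 15 pancreas markers (1 and 1). They included Foxa1 (0.81 ± 0.08), Cyp39a1 (−2.25 ± 0.13), Alas2 of haem synthesis (1.92 ± 0.17) and Prom1, a progenitor marker (−2.09 ± 0.20). None of the 9 B cell and plasma cell markers passed in limma (2 at an unadjusted p under 0.05, and 1 higher and 1 lower adjusted over the list alone). The median differed in sign from the mean and the test for the transcription factors and the red blood cell genes. Median centring turned the medians of the growth hormone (−0.03 to 0.01), cholangiocyte (−0.05 to 0.02) and red blood cell (−0.01 to 0.05) lists. Over the 26 lists, 15 passed with the preset correlation, 0 with an estimated one and 10 by fry. Called list members numbered 80 higher and 165 lower, and 44 and 65 without replicate 1. Replicate 2 also had 9 exocrine pancreas genes higher in the male pool, at a median of 3.46 against −0.13 on replicate 1, a subset chosen after its values were seen.

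In males at day 5 Afp and neutrophil genes rose and male-biased genes fell in the pools labelled Adeno-Cux2. Afp, alpha-fetoprotein of the fetal liver, rose by 5.08 ± 0.26 (33.8-fold), Prom1 by 3.14 ± 0.20, Akr1b7 by 3.11 ± 0.14 and Ccnd1 by 2.76 ± 0.10. The neutrophil genes S100a8 and Camp rose by 3.30 ± 0.12 and 3.18 ± 0.14, and the macrophage genes Chil3 by 3.14 ± 0.13 and Gpnmb 8.58-fold, although a further Gpnmb probe gave a log2 ratio of 0.23. The male-biased Cyp4a12a (−2.62 ± 0.20), Elovl3 (−2.36 ± 0.09), Slco1a1 (−2.30 ± 0.16) and Mup3 (−2.08 ± 0.27) fell. So did Kcnk1 (−2.09 ± 0.12), the sulfotransferase Sult2a8 (−2.06 ± 0.12), Raet1a (−2.01 ± 0.19), Hsd3b4 (−1.99 ± 0.18) and Obp2a (−1.95 ± 0.17). The female-biased Sult2a2 rose by 4.79 ± 0.96. In all, 3088 genes rose and 1100 fell of 22220, or 4188 (18.9%), 666 and 106 of them by at least 2-fold. Without replicate 1 the counts were 1020 and 145, and without replicate 2 they were 875 and 170. Those arrays also ended the calls of Sult2a2 (adjusted p = 0.157 and 0.257) and Mup3 (0.0667 and 0.0739), and that of Sult2a2 was lost without background subtraction (0.0684), with the software's log ratios (0.0684) and with an intensity trend (0.130).

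Known female-biased genes rose and known male-biased genes fell in males at day 5. Of 47 known female-biased genes 24 rose and 4 fell (28 and 6 adjusted over the list alone, median 0.74, adjusted p = 7.73e-06), with Tox at 1.64 ± 0.11 and Trim24 at 1.21 ± 0.08, while Adh6-ps1, male-biased in these mice, fell by 1.31. Female-biased genes had adjusted p = 0.199 with estimated correlation. Of 50 known male-biased genes 28 fell and 1 rose (2 higher and 31 lower adjusted over the list alone, median −0.83, adjusted p = 4.3e-19), and all 6 genes of the urinary protein list fell (6 alone, median −1.78, adjusted p = 2.69e-06). Both lists had adjusted p = 0.199 with estimated correlation. Of 17 growth hormone signalling genes 7 rose, among them Igfbp2 (1.43 ± 0.13), but the list missed the set test (8 higher and 1 lower adjusted over the list alone, adjusted p = 0.193). Of 33 liver transcription factors 4 rose and 3 fell (4 and 6 adjusted over the list alone, median −0.12, adjusted p = 0.0395). Transcription factors had adjusted p = 0.199 with estimated correlation.

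Interferon-stimulated, acute-phase and p53 target genes rose in males at day 5. Of 43 interferon-stimulated genes 36 rose (40 adjusted over the list alone, median 0.82, adjusted p = 4.3e-19), including Ifi44 (1.88 ± 0.07) and Oas2 (1.64 ± 0.07), whose further probes gave 0.88 and 0.13. Interferon genes had adjusted p = 0.199 with estimated correlation. Of 28 acute-phase genes 14 rose and 2 fell (19 and 2 adjusted over the list alone, median 0.44, adjusted p = 5.54e-06), with Lcn2 at 2.25 ± 0.08, and of 22 p53 targets 16 rose and 1 fell (16 and 1 alone, median 0.44, adjusted p = 3e-06), with Pmaip1, a pro-apoptotic gene, at 2.18 ± 0.13. Both lists had adjusted p = 0.199 with estimated correlation. Of 43 cell cycle genes 19 rose and 2 fell (22 and 2 adjusted over the list alone, median 0.28, adjusted p = 3.91e-05). Cell cycle genes had adjusted p = 0.294 with estimated correlation. Of 26 unfolded protein response genes 3 rose, among them asparagine synthetase Asns (2.02 ± 0.18), and 5 fell (3 higher and 5 lower adjusted over the list alone, median −0.14, adjusted p = 0.0383). Unfolded protein genes had adjusted p = 0.199 with estimated correlation.

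Markers of other cell types also rose in males at day 5. Macrophage markers rose in 22 of 25 (24 higher and 1 lower adjusted over the list alone, median 1.35, adjusted p = 4.3e-19), with Lyz1 at 2.10 ± 0.07, and neutrophil markers in 12 of 14 (13 alone, median 1.66, adjusted p = 9.86e-12). Both lists had adjusted p = 0.199 with estimated correlation. Of 26 T and natural killer markers 16 rose (17 adjusted over the list alone, median 0.44, adjusted p = 5.34e-08), including granzyme A, Gzma (1.63 ± 0.14), and Klra7 (1.41 ± 0.07), and endothelial markers in 7 of 19 (11 alone, median 0.21, adjusted p = 7.83e-05). Both lists had adjusted p = 0.199 with estimated correlation. Which cells of these scid mice carried the immune cell markers was not tested. Stellate cell markers rose in 17 of 22 (18 adjusted over the list alone, median 0.75, adjusted p = 1.24e-09), with collagen Col1a1 at 1.87 ± 0.19, and cholangiocyte and progenitor markers in 8 of 17 (9 alone, median 0.33, adjusted p = 3.31e-05). Stellate markers had adjusted p = 0.241 with estimated correlation, and cholangiocyte markers 0.30. Of 15 red blood cell genes 7 rose, with Eraf at 1.39 ± 0.09, and 2 fell, with Alas2 at −1.47 ± 0.17 (8 and 2 adjusted over the list alone, median 0.39, adjusted p = 0.0178). Red blood cell genes had adjusted p = 0.199 with estimated correlation. Skeletal muscle markers, added after the values were seen, had medians of 0.11 and 0.86 on the 2 arrays, and 2 of 46 were called higher.

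Fatty acid synthesis genes in males at day 5 fell in 6 of 27 and rose in 2 (2 higher and 7 lower adjusted over the list alone, median −0.19, adjusted p = 0.00523), the desaturase Scd2 rising by 2.57 ± 0.12. Fatty acid genes had adjusted p = 0.403 with estimated correlation. Complement and coagulation genes fell in 7 of 34 and rose in 4 (4 higher and 9 lower adjusted over the list alone, median −0.06, adjusted p = 0.0399). Complement genes had adjusted p = 0.519 with estimated correlation. In the lists that missed the set test (adjusted p = 0.0691 to 0.339), the members that rose and fell were 8 and 12 of 39 PPAR-alpha genes (9 and 15 adjusted over the list alone), 16 and 5 of 36 xenobiotic genes (16 and 8), 5 and 7 of 29 bile acid genes (6 and 9), 6 and 3 of 30 hepatocyte genes (6 and 3), 5 and 0 of 9 B cell markers (5 and 1) and 0 and 1 of 15 pancreas markers (0 and 1). They included Pdk4 (2.09 ± 0.20) and Vnn1 (−1.96 ± 0.20), Cyp2c55 (2.31 ± 0.13) and Aldh1a1 (−1.40 ± 0.10), and the transporters Abcc4 (2.32 ± 0.13) and Slco1a4 (2.83-fold). None of the 25 cholesterol genes passed in limma (2 at an unadjusted p under 0.05, and none adjusted over the list alone). Median and mean differed in sign for the PPAR-alpha list (−0.13 and 0.09) and the cholesterol list. Median centring turned the cholesterol median (0.01 to −0.04), as the software's log ratios did (−0.03). Of 26 lists 18 passed with the preset correlation, 0 with an estimated one and 17 by fry. List members called numbered 353, and 140 without replicate 1 and 138 without replicate 2.

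In females at day 5 the pools labelled Adeno-Cux2, in which Cux2 itself was lower, shared much of the male response. Afp rose by 5.41 ± 0.26 (42.6-fold), as did Igf2 (3.11 ± 0.15), Akr1b7 (2.80 ± 0.14), Gpnmb (2.60 ± 0.07, and 0.20 on a further probe) and Ccnd1 (2.59 ± 0.10). Others that rose were Tinag (2.91 ± 0.13), S100g (2.83 ± 0.26), Plet1 (2.59 ± 0.12) and lipoprotein lipase Lpl (2.21 ± 0.13). The urinary protein genes Mup6, Mup1, Mup5 and Mup4 fell (−4.28 ± 0.30, −4.24 ± 0.29, −3.87 ± 0.25 and −3.13 ± 0.23). So did the sulfotransferases Sult3a1 (−5.72 ± 1.27) and Sult3a2 (−4.07 ± 0.78), the muscle gene Myl1 (−3.76 ± 0.41), Cck (−3.39 ± 0.58), Rgs16 (−3.14 ± 0.30) and Rsph4a of motile cilia (−2.76 ± 0.07). In all, 2849 genes rose and 1401 fell, or 4250 (19.1%), 341 and 131 by at least 2-fold. Of the male day 5 calls, 2190 were higher and 598 lower in females too, against 395.9 and 69.36 by chance. Opposite were 22 against 335.7, and the Pearson r across genes was 0.716. The chance values, here and at day 3, ignore the gene variance that comparisons share and may be too low. Without replicate 1 the counts were 959 and 385, without replicate 2 they were 1639 and 585, and 874 fell without either male day 5 array. Calls were lost for Sult3a1 and Sult3a2 without replicate 1 (−3.01 and −2.41, adjusted p = 0.325 and 0.202, against −8.43 and −5.73 without replicate 2), with the software's log ratios (0.123 and 0.108), with the slide's 4 arrays alone (0.0844 and 0.0670) and with an intensity trend (0.156 and 0.114), and for Sult3a1 without either male day 5 array (0.0532). They were also lost for Cck without either own array (0.110 and 0.0745), with the software's log ratios (0.0699), without a dye term (0.0514) and with an intensity trend (0.0781), and for Myl1 with the software's log ratios (0.0867).

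Male-biased genes fell in females as well. Of 50 known male-biased genes 22 fell and 5 rose (5 higher and 24 lower adjusted over the list alone, median −0.32, adjusted p = 2.38e-08), with Slco1a1 at −2.43 ± 0.16, and all 6 genes of the urinary protein list fell (6 alone, median −3.50, adjusted p = 1.38e-08). Male-biased genes had adjusted p = 0.344 with estimated correlation, and urinary protein genes 0.276. Known female-biased genes went both ways, 9 rising and 11 falling of 47 (11 higher and 13 lower adjusted over the list alone, adjusted p = 0.0820). Skeletal muscle markers, added after the values were seen, lay at medians of −0.46 and −1.56 on the 2 arrays, with 23 of 46 called lower. On replicate 1 the 9 exocrine pancreas genes, also chosen after their values were seen, had a median of 4.27, and on replicate 2 of −0.95.

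Markers of immune, stellate and progenitor cells rose in females at day 5 with interferon and cell cycle genes. Of 25 macrophage markers 20 rose (22 higher and 1 lower adjusted over the list alone, median 0.84, adjusted p = 8.24e-15), and of 14 neutrophil markers 11 rose (12 alone, median 1.15, adjusted p = 1.07e-08), S100a8 by 1.86 ± 0.12 and Camp by 2.20 ± 0.14. Both lists had adjusted p = 0.276 with estimated correlation. Of 43 interferon-stimulated genes 25 rose (31 adjusted over the list alone, median 0.49, adjusted p = 5.73e-12), Oas2 by 1.37 ± 0.07, with 0.08 on a further probe, and Oasl2 by 1.31 ± 0.10. Interferon genes had adjusted p = 0.344 with estimated correlation. Of 22 stellate cell markers 16 rose (18 adjusted over the list alone, median 0.67, adjusted p = 3.63e-08), Col1a1 by 1.71 ± 0.19. Stellate markers had adjusted p = 0.396 with estimated correlation. Cholangiocyte and progenitor markers rose in 11 of 17 (13 adjusted over the list alone, median 0.71, adjusted p = 2.38e-08), with osteopontin, Spp1, at 2.11 ± 0.17 and the glypican Gpc3 of fetal liver at 2.17 ± 0.22. Cholangiocyte markers had adjusted p = 0.344 with estimated correlation. Endothelial markers rose in 9 of 19 (14 adjusted over the list alone, median 0.28, adjusted p = 3.03e-05), with Plvap at 0.81 ± 0.10, T and natural killer markers in 10 of 26 (13 alone, median 0.22, adjusted p = 0.0018), and red blood cell genes in 8 of 15, with 1 falling (8 and 1 alone, median 0.38, adjusted p = 0.00789) and Eraf at 1.14 ± 0.09. Endothelial markers and red blood cell genes had adjusted p = 0.276 with estimated correlation, and T cell markers 0.459. Of 43 cell cycle genes 25 rose and 3 fell (28 and 5 adjusted over the list alone, median 0.34, adjusted p = 0.0018), with Bub1 at 0.84 ± 0.07 and cyclin E2, Ccne2, at −0.84 ± 0.07. Cell cycle genes had adjusted p = 0.488 with estimated correlation. Of 22 p53 targets 9 rose and 1 fell (9 and 2 adjusted over the list alone, median 0.13, adjusted p = 0.0323), Pmaip1 by 1.70 ± 0.13, although the list missed the threshold without a dye term (adjusted p = 0.0508). The p53 targets had adjusted p = 0.506 with estimated correlation.

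Metabolic lists fell in part in females at day 5. Of 29 bile acid genes 10 fell, Cyp8b1 by 1.97, and 4 rose, Abcc4 by 1.76 ± 0.13 (5 higher and 13 lower adjusted over the list alone, median −0.21, adjusted p = 0.0301), with an adjusted p of 0.0508 without a dye term. Bile acid genes had adjusted p = 0.459 with estimated correlation. PPAR-alpha and fatty acid oxidation genes fell in 10 of 39 and rose in 3, Acot1 by 1.40 ± 0.14 (3 higher and 12 lower adjusted over the list alone, median −0.15, adjusted p = 0.000826). PPAR-alpha genes had adjusted p = 0.344 with estimated correlation. Fatty acid synthesis genes fell in 6 of 27 and rose in 2, Scd2 by 2.58 ± 0.12 (3 higher and 8 lower adjusted over the list alone, median −0.17, adjusted p = 0.0379). Fatty acid genes had adjusted p = 0.634 with estimated correlation. Complement and coagulation genes fell in 7 of 34 and rose in 4 (4 higher and 7 lower adjusted over the list alone, median −0.09, adjusted p = 0.0409). Complement genes had adjusted p = 0.634 with estimated correlation. In the other lists (adjusted p = 0.0780 to 0.776), the members that rose and fell were 9 and 8 of 36 xenobiotic genes (13 and 8 adjusted over the list alone), 5 and 5 of 28 acute-phase genes (9 and 5), 6 and 5 of 30 hepatocyte genes (9 and 5), 3 and 5 of 33 transcription factors (3 and 9), 3 and 3 of 17 growth hormone genes (3 and 4), 1 and 2 of 26 unfolded protein genes (1 and 1), 3 and 1 of 9 B cell markers (3 and 1) and 1 and 1 of 15 pancreas markers (1 and 1). They included Cyp2c55 (2.39 ± 0.13), Cyp2c54 (−1.63 ± 0.16), Aldh1a1 (−1.52 ± 0.10), Orm3 (−1.21 ± 0.11) and Asns (1.99 ± 0.18). None of the 25 cholesterol genes passed in limma (4 at an unadjusted p under 0.05, and none adjusted over the list alone), with Tm7sf2 at −0.41 ± 0.14 (adjusted p = 0.0909, and 0.0101 without replicate 2). Median and mean differed in sign for the growth hormone and B cell lists, and the B cell median of −0.02 was 0.04 with the software's log ratios and just above 0 without background subtraction. Of 26 lists 16 passed with the preset correlation, 0 with an estimated one and 13 by fry. List members called numbered 309, against 156 without replicate 1 and 197 without replicate 2.

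**Figure D2:**
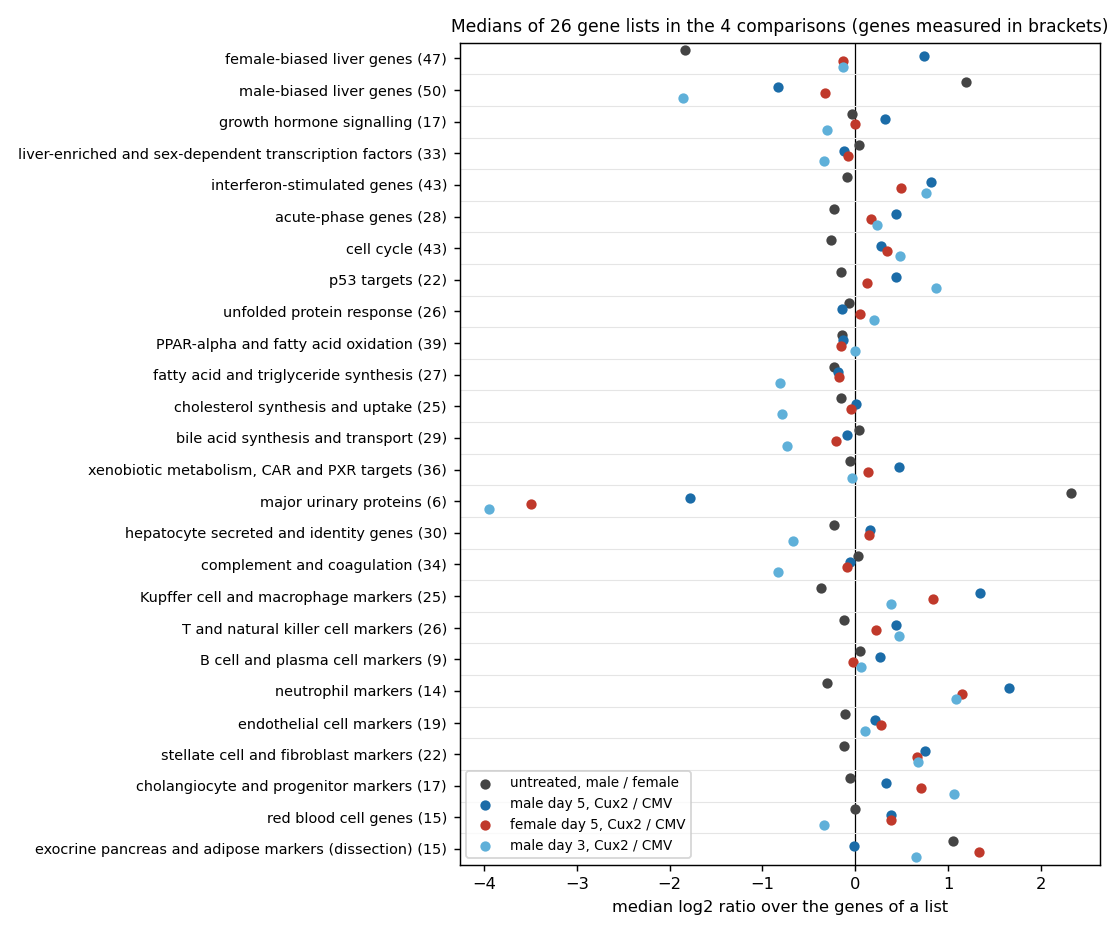
Median log2 ratio of the genes of each of 26 lists in the 4 comparisons. The urinary protein list medians are 2.33 in untreated mice and −1.78, −3.50 and −3.95 in males at day 5, females at day 5 and males at day 3.

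In males at day 3 Afp rose and hepatocyte genes fell widely. Afp rose by 5.56 ± 0.26 (47-fold), Csn3 by 4.22 ± 0.26, S100g by 4.18 ± 0.26, Prom1 by 3.89 ± 0.20 and Asns by 3.49 ± 0.18. The annexin Anxa3 rose by 3.46 ± 0.19, Pdk4 by 3.41 ± 0.20, Akr1b7 by 3.16 ± 0.14 and Plat by 3.53 ± 0.27, for which the lowest of its 3 probes gave 0.52. Mup1, Mup6, Mup5 and Mup3 fell (−4.42 ± 0.29, −4.40 ± 0.30, −4.19 ± 0.25 and −3.71 ± 0.27). So did Sult2a8 (−4.35 ± 0.12), Slco1a1 (−3.92 ± 0.16), Elovl3 (−3.71 ± 0.09) and Kcnk1 (−3.54 ± 0.12). In all, 5274 genes rose and 4508 fell, or 9782 (44.0%), 1064 and 678 by at least 2-fold. The higher share was 53.9%, against 68.5% with median centring (6082 and 2793) and 46.8% with the software's log ratios (4479 and 5082). Of the male day 5 calls, 2537 were higher and 938 lower at day 3 too, against 732.9 and 223.2 by chance, and 100 were opposite against 887.6 (Pearson r of 0.745 across genes). Without replicate 1 the counts were 3248 and 2715, and without replicate 2 they were 3136 and 2288. On replicate 2 Xist stood at −3.28, against 0.11 on replicate 1, which is more Xist in its CMV pool.

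Known male-biased genes fell in males at day 3. Of 50 male-biased genes 43 fell and 2 rose (2 higher and 44 lower adjusted over the list alone, median −1.86, adjusted p = 1.32e-19), with Wfdc2 at 0.88 ± 0.07 and carbonic anhydrase Car3 at −2.25 ± 0.17, and all 6 genes of the urinary protein list fell (6 alone, median −3.95, adjusted p = 1.81e-05). Both lists had adjusted p = 0.264 with estimated correlation. Of 47 female-biased genes 19 rose, Tox by 2.05 ± 0.11 and Trim24 by 1.91 ± 0.08, and 13 fell, Adh6-ps1 by 1.95 (19 higher and 14 lower adjusted over the list alone, adjusted p = 0.523). The median of that list was −0.13, while its mean and test were above 0, the median was just above 0 with median centring, and it was 0.48 without replicate 2, with 20 genes higher and 9 lower. Of 17 growth hormone signalling genes 6 rose, Igfbp1 by 3.26 ± 0.44, and 8 fell, Igfbp2 by 1.96 and Ghr by 1.36 (6 and 8 adjusted over the list alone, adjusted p = 0.378). Of 33 liver transcription factors 17 fell, Ppara by 1.31 and Cebpa by 1.24, and 4 rose (4 higher and 18 lower adjusted over the list alone, median −0.33, adjusted p = 0.00251). Transcription factors had adjusted p = 0.264 with estimated correlation.

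**Figure D3:**
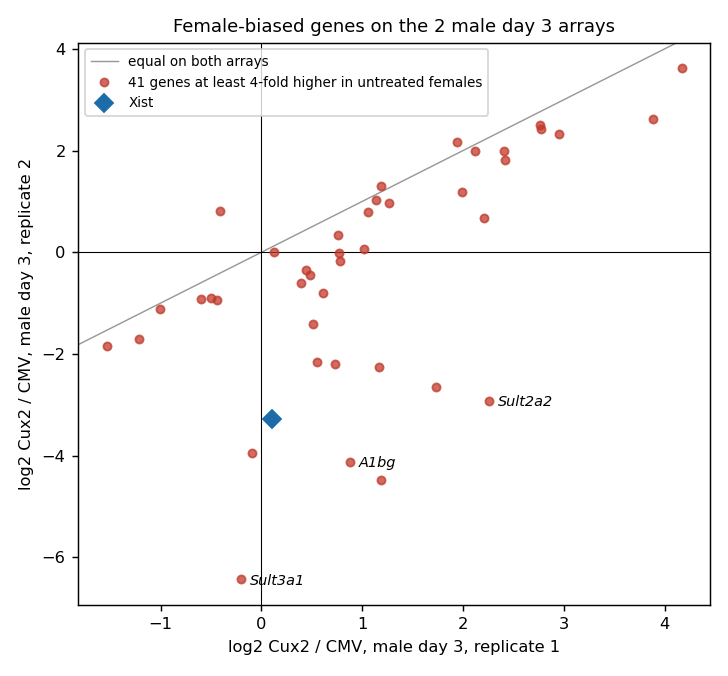
Log2 ratios of 41 genes at least 4-fold higher in untreated females, with Xist as a diamond, on replicate 1 (horizontal) and replicate 2 (vertical) of the male day 3 arrays. Of the 41 genes, 38 lie lower on replicate 2.

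Hepatocyte lists fell together in males at day 3. Of 34 complement and coagulation genes 25 fell, C9 by 2.59 and C8a by 2.35, and 1 rose (1 higher and 26 lower adjusted over the list alone, median −0.84, adjusted p = 2.74e-10). Complement genes had adjusted p = 0.264 with estimated correlation. Of 30 hepatocyte identity genes 21 fell, glucose-6-phosphatase G6pc by 2.64 and Otc by 2.49, and 2 rose (3 higher and 21 lower adjusted over the list alone, median −0.67, adjusted p = 4.02e-06). Hepatocyte genes had adjusted p = 0.292 with estimated correlation. Of 29 bile acid genes 20 fell, Cyp8b1 by 3.50, and 4 rose, including Abcc4 (2.65 ± 0.13) and Slc51b (2.41 ± 0.13) (4 higher and 20 lower adjusted over the list alone, median −0.73, adjusted p = 4.39e-06). Bile acid genes had adjusted p = 0.264 with estimated correlation. Of 25 cholesterol genes 19 fell, Tm7sf2 by 1.75 (20 adjusted over the list alone, median −0.78, adjusted p = 4.31e-07), with 8 falling without replicate 2. Cholesterol genes had adjusted p = 0.401 with estimated correlation. Of 27 fatty acid synthesis genes 21 fell, Thrsp by 2.43 and the elongase Elovl6 by 1.87, and 2 rose, Scd2 by 2.49 ± 0.12 (2 higher and 23 lower adjusted over the list alone, median −0.81, adjusted p = 1.16e-06), with 12 falling without replicate 2. Fatty acid genes had adjusted p = 0.280 with estimated correlation. Of 15 red blood cell genes 9 fell, Alas2 by 2.90 and the globin Hba-a1 by 2.73, and 1 rose (1 higher and 9 lower adjusted over the list alone, median −0.34, adjusted p = 0.00107). Red blood cell genes had adjusted p = 0.264 with estimated correlation. Members that rose and fell in lists that missed the set test were 16 and 13 of 39 PPAR-alpha genes (16 and 13 adjusted over the list alone) and 10 and 16 of 36 xenobiotic genes (13 and 16), at an adjusted p of 0.990 and 0.322. The thioesterase Acot2 stood at 2.74 ± 0.19 and Cyp2c54 and Cyp2c37 at −3.28 ± 0.16 and −2.35 ± 0.11. Median and test differed in sign for the PPAR-alpha list. Without replicate 2 the xenobiotic median of −0.04 was 0.18 and the PPAR-alpha median of 0.00 was −0.08, the former also turning with median centring (0.05) and without background subtraction (0.01).

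Cell cycle, stress, interferon and immune lists rose in males at day 3. Of 43 cell cycle genes 35 rose, Ccnd1 by 2.95 ± 0.10 and ribonucleotide reductase Rrm2 by 1.15 ± 0.10 (37 adjusted over the list alone, median 0.49, adjusted p = 1.07e-09), with 21 rising without replicate 2. Cell cycle genes had adjusted p = 0.264 with estimated correlation. Of 22 p53 targets 20 rose, Pmaip1 by 3.03 ± 0.13 and Btg2 by 1.40 ± 0.17, and 1 fell (20 and 1 adjusted over the list alone, median 0.87, adjusted p = 1.23e-08). The p53 targets had adjusted p = 0.264 with estimated correlation. Unfolded protein response genes rose in 10 of 26, Atf3 by 2.33 ± 0.19 (10 adjusted over the list alone, median 0.20, adjusted p = 0.0128). Unfolded protein genes had adjusted p = 0.264 with estimated correlation. Of 43 interferon-stimulated genes 37 rose, the chemokine Cxcl10 by 2.55 ± 0.21 and Ifi44 by 2.07 ± 0.07, and 1 fell (39 and 1 adjusted over the list alone, median 0.76, adjusted p = 3.82e-13). Interferon genes had adjusted p = 0.280 with estimated correlation. Of 28 acute-phase genes 14 rose, Il1rn by 3.00 ± 0.18 and Cd14 by 2.80 ± 0.14, and 5 fell, Crp by 1.86 (14 and 5 adjusted over the list alone, median 0.23, adjusted p = 0.0242), the list missing the threshold without a dye term (adjusted p = 0.0971). Acute-phase genes had adjusted p = 0.444 with estimated correlation. Of 25 macrophage markers 14 rose, Gpnmb by 3.17 ± 0.07 (0.24 on a further probe), and 7 fell, the Kupffer cell genes Clec4f and Vsig4 by 2.23 and 1.90 (14 and 7 adjusted over the list alone, median 0.38, adjusted p = 0.00486). Macrophage markers had adjusted p = 0.359 with estimated correlation. Of 26 T and natural killer markers 18 rose, Klra7 by 1.86 ± 0.07 and Gzma by 1.44 ± 0.14, and 1 fell (18 and 1 adjusted over the list alone, median 0.47, adjusted p = 1.38e-05), and of 14 neutrophil markers 10 rose, myeloperoxidase Mpo by 2.54 ± 0.12, and 1, Fpr1, fell by 1.42 (10 and 1 alone, median 1.09, adjusted p = 0.000805). Both lists had adjusted p = 0.280 with estimated correlation.

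Of 22 stellate cell markers 13 rose, vimentin, Vim, by 2.48 ± 0.09 and thrombospondin Thbs1 by 2.01 ± 0.20 (0.25 on the lowest of its 3 probes), and 2 fell (15 and 2 adjusted over the list alone, median 0.68, adjusted p = 0.00035). Stellate markers had adjusted p = 0.444 with estimated correlation. Cholangiocyte and progenitor markers rose in 11 of 17 and fell in 1 (12 and 1 adjusted over the list alone, median 1.06, adjusted p = 8.85e-05). Cholangiocyte markers had adjusted p = 0.359 with estimated correlation. In the remaining lists (adjusted p = 0.413 to 0.630) the members that rose and fell were 5 and 3 of 19 endothelial markers (5 and 2 adjusted over the list alone), 2 and 1 of 9 B cell markers (2 and 1) and 1 and 1 of 15 pancreas markers (1 and 1), including Lyve1 (0.99 ± 0.08), Jchain (−0.88 ± 0.07) and Fabp4 (0.66 ± 0.08). The pancreas and adipose median of 0.66 was −0.34 without replicate 2, on which 9 exocrine pancreas genes had a median of 2.81 against 0.05 on replicate 1, while the muscle medians were −0.01 and 0.30. Of 26 lists 19 passed with the preset correlation, 0 with an estimated one and 23 by fry. Called list members were 257 higher and 255 lower, and 206 and 192 without replicate 2.

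Genes called as sex-biased also responded to the treatment. These sets come from untreated arrays of the same model and share its gene variances. At day 5 in males 646 of 1366 female-biased genes rose and 77 fell (47.3% and 5.64%, against 11.7% and 4.91% of other genes, adjusted p = 5.28e-18). Of 1097 male-biased genes 343 fell and 42 rose (adjusted p = 3.09e-22). Both sets had adjusted p = 0.216 with estimated correlation. In females at day 5, 474 female-biased genes rose and 185 fell (adjusted p = 0.000444), and 144 male-biased genes fell and 83 rose (adjusted p = 0.00531). These sets had adjusted p = 0.422 and adjusted p = 0.482 with estimated correlation. In males at day 3, 683 and 266 female-biased genes rose and fell (adjusted p = 2.16e-06), and 574 male-biased genes fell and 108 rose (adjusted p = 5.44e-15). Here they had adjusted p = 0.350 and adjusted p = 0.216 with estimated correlation. By fry 5 of these 6 sets passed, the male-biased set in females standing at an adjusted p of 0.243. Of 162 female-biased genes of at least 2-fold 91, 32 and 72 rose and 9, 43 and 33 fell in males at day 5, females at day 5 and males at day 3. Of 160 male-biased ones 4, 13 and 5 rose and 125, 45 and 136 fell.

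Across the 22220 genes the sex difference and the response had a Pearson r of −0.424 in males at day 5, −0.0949 in females at day 5 and −0.269 in males at day 3. They share the untreated arrays, whose removal moved them: without untreated replicate 1 they were −0.316, 0.0296 and −0.133, the female value changing sign, and it was −0.178 without untreated replicate 2. Without replicate 1 or 2 of the male day 5 arrays the male day 5 value was −0.360 or −0.457, and without those of day 3 the day 3 value was −0.184 or −0.341. Without untreated replicate 1, fewer genes were called sex-biased, and those that rose and fell in males at day 5 were 134 and 30 of the female-biased and 19 and 192 of the male-biased. Under the same removal they were 75 and 71, and 26 and 68, in females at day 5, and 118 and 61, and 19 and 200, in males at day 3. Without untreated replicate 2 they were 977 and 122 of the female-biased in males at day 5, 757 and 265, and 139 and 263, in females, and 1206 and 439, and 160 and 867, in males at day 3. Without replicate 1 or 2 of the male day 5 arrays, 188 and 5 or 190 and 9 female-biased genes, and 7 and 63 or 5 and 97 male-biased genes, rose and fell in males at day 5. Without either of those arrays they were 204 and 84, and 40 and 81, in females, and 315 and 115, and 39 and 329, in males at day 3. Without replicate 1 or 2 of the female arrays they were 230 and 65 or 297 and 86, and 29 and 58 or 49 and 87, in females. Without replicate 1 or 2 of day 3 they were 411 and 187 or 454 and 136, and 45 and 327 or 42 and 330, in males at day 3.

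The female response at day 5 was tested against the male one. Rsph4a had the lowest adjusted p of the genes named here, at −2.72 ± 0.10 (adjusted p = 0.00102). Its ratios were −2.78 and −2.74 in females and 0.02 and −0.09 in males, who start at least 4-fold lower with less room to fall. The muscle genes Myl1, Acta1 and Apobec2 were lower in the female response, at −4.87 ± 0.59, −4.59 ± 0.56 and −2.97 ± 0.31 (adjusted p = 0.0490, 0.0490 and 0.0361). Kcnk1 (1.46 ± 0.16), Meig1 (1.35 ± 0.16) and Ces4a (1.19 ± 0.11) were higher (adjusted p = 0.0475, 0.0490 and 0.0307), and Cux2 was lower at −1.22 ± 0.12 (adjusted p = 0.0341). In all, 8 genes were higher and 38 lower in the female response, with 2359 genes at an unadjusted p under 0.05. Without male day 5 replicate 1 or 2 the number was 0 in limma, with 1265 and 1236 genes at an unadjusted p under 0.05, and these 8 genes stood at an adjusted p of 0.0657 to 0.377. The number was also 0 with the software's log ratios (2145 unadjusted), where they stood at 0.252 to 0.400, while 2 were higher and 40 lower without female replicate 1, and 15 and 12 without female replicate 2.

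Single calls of this difference were lost elsewhere. Without background subtraction all but Rsph4a were lost (adjusted p = 0.105 to 0.239), with Apobec2 at −1.03, Meig1 at 0.46, Cux2 at −0.46 and Ces4a at 0.68, while the software's log ratios gave −6.85, 2.50, −2.69 and 0.92. Without female replicate 1 Kcnk1, Meig1, Ces4a, Myl1 and Cux2 were lost (0.0623 to 0.0758). Without female replicate 2 Ces4a, Myl1, Acta1, Apobec2 and Cux2 were lost (0.0508 to 0.124), without either male day 3 array Kcnk1 and Meig1 (0.0692 and 0.0731), and without either untreated array Myl1 and Acta1 (0.0553 and 0.0682). With median centring Ces4a and Cux2 were lost (0.0808 and 0.146), with the mean of all probes Myl1 and Acta1 (both 0.0527), without a dye term Kcnk1, Meig1 and Ces4a (0.0508 to 0.0997), with a dye term per slide Meig1, Myl1, Acta1 and Apobec2 (0.0589 to 0.0701) and with an intensity trend Myl1 and Acta1 (0.143 and 0.131).

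Lists differed between the female and male responses at day 5 by the preset correlation alone. Known female-biased genes were lower in the female response, 4 called and 1 higher of 47 (3 higher and 32 lower adjusted over the list alone, median −0.83, adjusted p = 3.97e-16), and known male-biased genes higher, with 1 called (14 higher and 6 lower alone, median 0.29, adjusted p = 3.5e-06). Female-biased genes had adjusted p = 0.256 with estimated correlation, and male-biased genes 0.359. Acute-phase genes were lower (2 called, 11 lower adjusted over the list alone, median −0.46, adjusted p = 9.36e-11), as were macrophage markers (0 called, 2 higher and 16 lower alone, median −0.46, adjusted p = 4.94e-11), T and natural killer markers (1 called, 12 lower alone, median −0.32, adjusted p = 8.16e-08) and neutrophil markers (1 called, 5 lower alone, median −0.41, adjusted p = 5.27e-07). These 4 lists had adjusted p = 0.282 with estimated correlation. Interferon-stimulated genes (1 called, 1 higher and 7 lower adjusted over the list alone, median −0.25, adjusted p = 1.66e-06), p53 targets (0 called, 4 lower alone, median −0.18, adjusted p = 1.99e-05), the urinary protein list (0 called, 4 lower alone, median −1.91, adjusted p = 1.05e-05) and growth hormone genes (0 called, 1 lower alone, median −0.19, adjusted p = 0.0157) also lay lower. Interferon genes had adjusted p = 0.532 with estimated correlation, p53 targets 0.304 and urinary protein genes and growth hormone genes 0.282. Unfolded protein response genes (0 called, 2 higher and 1 lower adjusted over the list alone, median 0.14, adjusted p = 0.000883), cholangiocyte markers (0 called, 1 lower alone, median 0.18, adjusted p = 0.0338) and pancreas and adipose markers (0 called, none alone, median 1.18, adjusted p = 0.0364) lay higher. Unfolded protein genes had adjusted p = 0.282 with estimated correlation, cholangiocyte markers 0.650 and pancreas markers 0.573. The 9 exocrine pancreas genes had medians of 4.27 and −0.95 on the female arrays and −0.02 and 0.03 on the male ones, so the pancreas difference rests on 1 array. Of these lists the growth hormone, p53, unfolded protein, urinary protein, macrophage, cholangiocyte and pancreas ones had 0 called in limma, with 4, 10, 7, 4, 18, 3 and 0 members at an unadjusted p under 0.05. By fry 0 of the 26 lists passed (lowest adjusted p = 0.0656), but without the dye term the female-biased (0.0319) and macrophage lists (0.0354) did. In limma 2 list members were called higher and 11 lower. In the other 13 lists (adjusted p = 0.0901 to 0.984) a bile acid gene and a transcription factor were called lower. The signs of median, mean and test differed for the transcription factor, cell cycle, complement and red blood cell lists, whose medians lay within 0.02 of 0.

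The male response at day 5 was also tested against that at day 3. Expression relative to control was higher at day 5 for the globin gene Hbb-bt (3.83 ± 0.18), Dct (3.44 ± 0.18), Igfbp2 (3.39 ± 0.18) and Slc22a26 (3.36 ± 0.83). It was lower at day 5 for Cidec (−2.66 ± 0.20), Vnn1 (−2.02 ± 0.28) and Fbp2 (−2.01 ± 0.14), with adjusted p = 0.00102 to 0.0457 over the 7 genes. Cux2 did not pass (0.11 ± 0.12, adjusted p = 0.618). In all, 1802 genes were higher and 1075 lower at day 5, 439 and 148 by at least 2-fold. The higher share was 62.6%, and 36.8% with median centring (772 and 1323). The total of 2877 was 129 or 36 without male day 5 replicate 1 or 2 and 1049 or 571 without day 3 replicate 1 or 2. Slc22a26 stood at 1.17 and −2.26 on the day 3 arrays, the second being that with low Xist, and its difference was 5.09 without replicate 1 and 1.63 without replicate 2 of day 3. Of the 7 genes, it was lost without either male day 5 array (adjusted p = 0.186 and 0.283), without either untreated array (0.0550), without background subtraction (0.101), and with the software's log ratios (0.185), a dye term per slide (0.0514) and an intensity trend (0.184). Vnn1 was lost without male day 5 replicate 1 (0.0966) or 2 (0.0625), without day 3 replicate 2 (0.0607) and with the software's log ratios (0.0535), and Fbp2 without male day 5 replicate 2 (0.0515).

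Hepatocyte lists lay higher at day 5 than at day 3 in males. Complement and coagulation genes were higher in 22 of 34 (26 adjusted over the list alone, median 0.71, adjusted p = 7.62e-14), hepatocyte identity genes in 18 of 30 (23 alone, median 0.73, adjusted p = 3.94e-12), bile acid genes in 18 of 29 (19 and 3 alone, median 0.75, adjusted p = 1.22e-07) and male-biased genes in 35 of 50 (36 and 1 alone, median 1.18, adjusted p = 2.45e-16). These 4 lists had adjusted p = 0.227 with estimated correlation. Cholesterol genes (10 called, 16 adjusted over the list alone, median 0.66, adjusted p = 3.18e-08), fatty acid synthesis genes (10 and 1 called, 14 and 1 alone, median 0.63, adjusted p = 1.81e-05), xenobiotic genes (12 and 3 called, 17 and 3 alone, median 0.43, adjusted p = 0.000294) and the urinary protein list (5 called, 5 alone, median 2.04, adjusted p = 0.000317) were higher as well. Cholesterol genes had adjusted p = 0.317 with estimated correlation, fatty acid genes 0.287, xenobiotic genes 0.227 and urinary protein genes 0.246. Of 15 red blood cell genes 11 were higher (12 adjusted over the list alone, median 0.73, adjusted p = 2.13e-08), and macrophage (15 and 2 called, 17 and 3 alone, median 0.68, adjusted p = 7.4e-07) and neutrophil markers (7 called, 10 higher and 1 lower alone, median 1.13, adjusted p = 4.87e-05) lay higher. Red blood cell genes had adjusted p = 0.127 with estimated correlation, and macrophage markers and neutrophil markers 0.227. Growth hormone genes (5 called, 6 adjusted over the list alone, median 0.22, adjusted p = 0.0344), transcription factors (5 and 2 called, 6 and 2 alone, median 0.27, adjusted p = 0.0328), endothelial markers (1 and 1 called, 1 and 1 alone, median 0.15, adjusted p = 0.0339) and female-biased genes (11 and 3 called, 20 and 4 alone, median 0.45, adjusted p = 0.0334) lay higher too. Growth hormone genes had adjusted p = 0.246 with estimated correlation, transcription factors 0.227 and endothelial markers and female-biased genes 0.307. Without day 3 replicate 2, on which Xist and female-biased genes were low, the female-biased median was 0.36, with 5 called higher and 1 lower. Lower at day 5 were unfolded protein response genes (9 called, 13 adjusted over the list alone, median −0.51, adjusted p = 1.82e-07), p53 targets (10 called, 1 higher and 15 lower alone, median −0.49, adjusted p = 3.18e-08), cell cycle genes (11 called, 12 alone, median −0.19, adjusted p = 3.61e-06) and interferon-stimulated genes (1 and 3 called, 1 higher and 2 lower alone, median −0.10, adjusted p = 0.0149). Unfolded protein genes had adjusted p = 0.127 with estimated correlation, p53 targets 0.227, cell cycle genes 0.253 and interferon genes 0.639. Of 26 lists 19 passed with the preset correlation, 0 with an estimated one and 18 by fry. In the 7 other lists (adjusted p = 0.0630 to 0.740) the median differed in sign from mean and test for T and natural killer markers. The medians of acute-phase genes (0.04), T and natural killer markers (0.02) and stellate cell markers (0.07) turned with median centring (−0.04, −0.10 and −0.07), the first 2 also without background subtraction (−0.01 and −0.02) and without day 3 replicate 2 (−0.05 and −0.10), where the pancreas and adipose median of −0.68 was 0.36. Called list members were 208 higher and 63 lower, and 28 and 2, 16 and 1, 125 and 25, and 80 and 20 without male day 5 replicate 1 or 2 and day 3 replicate 1 or 2.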

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

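The tests on the Y-linked genes, on exchanged pools and on the slope, and the allowance for spread in reading the muscle medians, were chosen after the result was seen. The patterns themselves were noticed in these data, so what follows are hypotheses.

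Responses that differed by a test between sexes or days come first. The female response at day 5 was higher than the male one for 8 genes and lower for 38, including Kcnk1 (1.46), Meig1 (1.35), Ces4a (1.19), Myl1 (−4.87), Acta1 (−4.59), Apobec2 (−2.97), Rsph4a (−2.72) and Cux2 (−1.22). The male response was higher at day 5 than at day 3 for 1802 genes and lower for 1075, including Hbb-bt (3.83), Dct (3.44), Igfbp2 (3.39), Slc22a26 (3.36, but 1.63 without day 3 replicate 2, the array with low Xist), Cidec (−2.66), Vnn1 (−2.02) and Fbp2 (−2.01). The arrays compared lie on different slides read with different software versions, so slide, pools and biology cannot be separated. The sex of the mice, with a lower start of female-biased genes such as Rsph4a in males, and the day stay open as biological explanations. Without either male day 5 array 0 genes differed between the sexes (limma, 1265 and 1236 at an unadjusted p under 0.05), and 129 or 36 between the days. Without female replicate 1 or 2 the female response was higher for 2 or 15 genes and lower for 40 or 12, and without day 3 replicate 1 or 2 the days differed in 1049 or 571.

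Cux2 was lower in the female pools labelled Adeno-Cux2 (−0.58 and −0.65) and higher in the male ones at day 5 (0.61 and 0.60). Exchanged pools or dyes would turn the whole female response, and its correlation with the male response across genes was 0.716. An inactive virus in the female pools would leave little response, and the slope of the female on the male response over 4188 genes called in males was 0.718. The correlation argues against an exchange as the whole cause. The slope cannot decide, since a response need not come from active Cux2. An inactive virus stays open, as do probes that read only the mouse's own Cux2 and a sex difference in its regulation.

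Xist stood at −3.28 on male day 3 replicate 2 and at 0.11 on replicate 1. A fault of a single probe is argued against by the 3 other Xist probes, which shifted by −0.63 to −2.39. Female RNA in the CMV pool of that array is a candidate explanation: 41 other genes at least 4-fold higher in untreated females shifted by a median of −0.62 (quartiles −1.53 and −0.32), 38 of them downwards, against −0.02 over all genes, and the Y-linked genes shifted by a median of 0.21 (0.16 to 0.27). The Xist shift would need 17.1% of female RNA in a pool of 6 mice, which predicts a Y-linked shift of 0.27. Other differences between the CMV pools in sex-dependent expression stay open for the female-biased genes, and no biological explanation was tested for Xist.

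Muscle genes were lower in the female pools labelled Adeno-Cux2. Muscle RNA in the male Adeno-Cux2 pools is argued against as the whole cause by the lower of the male day 5 medians over 46 markers, 0.11 (standard error 0.05), but the other was 0.86 (standard error 0.18) and 32 markers were above 0 on both arrays, so a part stays open. Muscle RNA in the female CMV pools may explain the pattern, with medians of −0.46 (standard error 0.12) and −1.56 (standard error 0.32). The first misses the bound of −0.5 set beforehand, and only an allowance for its spread over markers, added later, leaves this undecided. Of the 46 markers 37 were below 0 on both female arrays, Mb at −1.91 and −2.73, and 9 were not, Tpm2 at 0.47 and −0.67 among them.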

How the results depend on the processing

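All alternatives but fry without the dye term were chosen before the data were examined. The named genes were mostly chosen for calls that held without each array, so their stability is no measure. The series matrix gave the values of the software's log ratios throughout. Except where stated, the cause was not tested. Without background subtraction 843 genes were lower in untreated males and 1 differed between the sexes in response. With the software's log ratios 520 and 589 were higher and lower in untreated males, 1988 rose in males and 1644 in females at day 5, 0 differed between the sexes (2145 at an unadjusted p under 0.05, limma) and 649 between the days. Sex-biased genes, female-biased then male-biased, that changed were then 279 and 242 in males at day 5, 208 and 115 in females, and 389 and 388 at day 3. With median centring 718 were higher in untreated males, 2793 fell at day 3. Sex-biased genes that changed were then 469 and 251, 413 and 139, and, male-biased at day 3, 424. Without the dye term, that is without the replicate block, 21 differed between the sexes, while correlations of the replicate deviations between comparisons ran from −0.0945 to 0.296. With the 2 arrays alone 217 and 191 were higher and lower in untreated males, 2049 fell in males and 802 in females at day 5. With an intensity trend 101 differed between the sexes. A 1.5-fold threshold, which removes smaller changes by construction, left 395 and 487, 1560 and 313, 1229 and 413, 2376 and 1699 for the 4 comparisons, 1763 for the days, and 213 and 143, 148 and 82, and 238 and 208 sex-biased genes.

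Leaving out each array, with fewer samples by construction, gave 286 to 1562 higher and 249 to 2410 lower in untreated males, 875 to 3552 and 145 to 1511 in males at day 5, 959 to 3346 and 385 to 1863 in females. At day 3 it gave 3136 to 5833 and 2288 to 5057, 0 to 54 between the sexes and 36 to 3873 between the days. Changed sex-biased genes ran from 164 to 1099 and 70 to 540 in males at day 5, 146 to 1022 and 87 to 402 in females, and 179 to 1645 and 219 to 1027 at day 3. The correlations with the sex difference across genes ran from −0.457 to −0.316, from −0.178 to 0.0296 (the sign changed without untreated replicate 1) and from −0.341 to −0.133.

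Every list past the preset correlation missed with an estimated one. In untreated mice the adjusted p was then 0.179, 0.30, 0.469, 0.492, 0.509, 0.619, 0.663 or 0.726. In males at day 5 it was 0.199, 0.241, 0.294, 0.30, 0.403 or 0.519, and in females 0.276, 0.344, 0.396, 0.459, 0.488, 0.506 or 0.634. At day 3 it was 0.264, 0.280, 0.292, 0.359, 0.401 or 0.444, between the sexes 0.256, 0.282, 0.304, 0.359, 0.532, 0.573 or 0.650, and between the days 0.127, 0.227, 0.246, 0.253, 0.287, 0.307, 0.317 or 0.639. By fry the adjusted p missed in untreated mice for interferon and T cell (0.132), cholesterol (0.447), hepatocyte (0.110), neutrophil (0.0551) and stellate lists (0.308). In males at day 5 it missed for transcription factors (0.652), unfolded protein response (0.175), fatty acid synthesis (0.461) and complement (0.297), and in females for PPAR-alpha (0.0575), fatty acid synthesis (0.532), bile acid (0.0574) and complement (0.307). Between the sexes it missed for female-biased (0.0656), male-biased, growth hormone and interferon (0.225), acute-phase, T cell and neutrophil (0.0975), p53 (0.127), unfolded protein response (0.134), urinary protein (0.119), macrophage (0.0687), cholangiocyte (0.699) and pancreas lists (0.70), and between the days for interferon (0.470) and cholesterol (0.0812). It passed where the preset test did not for transcription factors in untreated mice (0.0484), growth hormone (0.0225), xenobiotic (0.0230) and B cell lists (0.00517) in males at day 5. It also passed for B cell markers in females (0.0423), female-biased (0.0229), growth hormone (0.0340), xenobiotic (0.0450) and endothelial lists (0.0367) at day 3, and B cell between the days (0.0155). Without the dye term p53 and bile acid lists missed in females (0.0508) and acute-phase at day 3 (0.0971), and PPAR-alpha passed between the sexes (0.0219), set against 21 genes without the replicate block. By fry without the dye term female-biased (0.0319) and macrophage lists (0.0354) passed between the sexes and cholesterol between the days (0.0438). Acute-phase and PPAR-alpha in untreated mice (0.0501), xenobiotic in males at day 5 (0.0776) and cell cycle in females (0.0622) then missed. So did growth hormone (0.125), acute-phase (0.0593) and xenobiotic (0.148) at day 3, and cell cycle (0.0597), xenobiotic (0.0531) and hepatocyte lists (0.0564) between the days. Set tests were not run with single arrays left out. Signal over background, with 68.2% to 80.1% of spots well above it, limits what is seen of dim genes.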

Other observations

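The tests on pancreas genes here were chosen after the result was seen, and no explanation was tested. Exocrine pancreas genes (Pnlip, Cpa1, Cpb1, Cel, Prss2, Cela1, Ctrb1, Amy2 and Pnliprp1), which encode digestive enzymes, differed between arrays of the same comparison. The median log2 ratio of these 9 genes on replicates 1 and 2 was −0.13 and 3.46 in untreated mice, −0.02 and 0.03 in males at day 5, 4.27 and −0.95 in females at day 5 and 0.05 and 2.81 in males at day 3.

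Single female-biased genes differed widely between the male day 3 arrays. On replicates 1 and 2, Sult3a1 stood at −0.20 and −6.43, Sult2a2 at 2.26 and −2.92, Slc22a26 at 1.17 and −2.26 and A1bg at 0.88 and −4.12, chosen after their values were seen.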
